A study of Arabidopsis thaliana with 6 samples.

How the data were processed

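The samples were 6 RNA-seq libraries from roots of Arabidopsis thaliana Col-0 seedlings aged 8 days, 3 from the apical 0.5 mm section (zone I) and 3 from the 1.5 mm section (zone II). Groups were taken from the sample titles. Per the labels' protocols, RNA was preserved before dissection, cDNA was made from a few nanograms of total RNA with a SMART-Seq template-switching kit and amplified by PCR, and libraries were made by tagmentation and sequenced as paired ends. Such libraries do not mark the strand, so reads from overlapping genes on opposite strands cannot be told apart, and the labels' protocols mention no molecular identifiers for PCR copies. The growth protocol in the labels also describes cell cultures and a mutant line that none of these 6 samples is labelled as.

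Per the submitters' processing notes, TopHat, Cufflinks and Cuffdiff were used with the TAIR10 genome. Their versions and settings are not given in the sources used here. TopHat aligns spliced reads, Cufflinks assembles transcripts and Cuffdiff tests differences between conditions. Where assembled loci join neighbouring genes, 1 value covers several genes, which was the case for 1021 of 33233 gene loci, and 107 loci named no gene. The gene and isoform comparisons covered different sets of loci, since the isoforms belonged to 33520 loci and the gene comparison had 33233. Whether they came from different assemblies is not stated in the sources used here.

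Both deposited tables hold 1 line per gene or isoform, with 1 value for each of 2 conditions, called control and experiment. No label of a sample uses either word, so neither condition was assigned to a zone, and the 2 columns of condition values in each table were not used here. The fold changes are log2 values of experiment over control, per the file headers and their layout in the authors' deposited tables. The deposited log2 column held 1852 infinite values and 1211 spreadsheet errors in the gene table, the latter in place of minus infinity, and such genes are said to be listed at 0 in one condition, with no fold. The test statistic is a score that the authors' Cuffdiff run gave, per the file headers. The p-value and q-value are those of the authors' Cuffdiff run, per the file headers. The deposited q-value was checked and equals the Benjamini-Hochberg adjustment over tested loci, with a largest relative difference of 4.9e-06 for genes and 4.96e-06 for isoforms. A gene or isoform was called changed at the authors' threshold, a q under 0.01. No count per library was analysed here, so the depth of each library and the precision it gives are unknown, no replicate could be left out, and no test was added to single genes.

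Gene identifiers were matched to the reference table of TAIR10.1 for symbols, and 28159 of 32105 loci of 1 named gene matched. Coordinates are those of the files on TAIR10, which count the start from 0, written here from 1. Of these loci 28158 overlapped the reference gene of the same name. Chromosome positions of reference genes were used for MIR779 and for the annotation of named genes.

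Gene lists were fixed before the data were examined, 18 by name with 227 members and 2 by description, as were the test, the threshold and the rule for named genes. For 220 of the 227 members the symbol was found at the locus in the reference table, and the other 7 are given by locus or are named as in the reference. Members on loci that could not be told from a neighbour or a duplicate (ARL2, PRP3, TIP2;2 and GAPA in the lists by name) were left out. Each list was tested with Fisher's exact test (two-sided) for its share of genes called higher, and separately lower, against all other tested genes, with Benjamini-Hochberg adjustment over 20 lists and both directions and a threshold of 0.05. The percentile of each list median was taken among 10000 random lists of the same size, with seed 1, not matched on expression. Members that pass when the deposited p is adjusted over the list alone are also given. The list test was tested on simulated data on 18050 genes, with lists of 8 to 29 members. In seeded lists, 70% of the members were drawn from genes called higher. Of these lists 78 of 80 were found (97.5%), and 0 of 640 tests of random lists passed. Random lists were drawn gene by gene, so this result does not cover lists whose members move together. Lists seeded for falls and lists outside these sizes were not simulated.

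Named genes were the 10 called genes with a symbol and a finite fold that had the largest rise and the 10 with the largest fall, up to 4 called and 2 uncalled members of each list with the largest absolute log2, every reference gene, every list member that went against its list, and genes with opposed isoforms. The written rule also asked for a minimum expression and for the genes of highest expression. Both need the condition values and were not applied, and uncalled members were taken by fold in place of expression. The ranking by test statistic, the naming of genes without a symbol, the organelle genes, the shares of calls by fold, and the test of gene families by shared description (123 families of 15 or more genes, against 17043 genes) were chosen after the data were seen. HRGP1 is reported as uncertain because of its neighbouring copy. Some genes that the rule selects are not reported here by name.

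Alternatives were q thresholds of 0.05 and 0.001, a minimum absolute log2 of 1 and centring of the fold changes. Added after the data were seen were protein-coding nuclear genes only, leaving out genes listed at 0 in one condition, a wider tolerance of 0.5 and centring when gene and isoform values were compared. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.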

Results

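RNA was sequenced from 2 neighbouring sections of the root apex of Arabidopsis thaliana Columbia (Col-0) seedlings, grown for 8 days under constant light. Zone I was the apical 0.5 mm, which holds the root cap and the dividing cells of the meristem. Zone II was a 1.5 mm section, which holds elongating cells and the cells that form root hairs. Each zone had 3 libraries, 6 in all. The design asks which genes and which transcript isoforms differ between the 2 sections. The values analysed here are a gene comparison and an isoform comparison that the authors had already made, and the labels of all 6 libraries name both. Whether both were made with the same settings is not stated in the sources used here. The conditions compared are called control and experiment, and which zone each name stands for is not stated in the sources used here. Of mitosis genes 16 of 25 tested and of root cap genes 5 of 10 tested were called lower in the experiment condition, and none higher. Of 18 tested root hair genes 10 were called higher and 1 lower. These values argue against the experiment condition being zone I. No label settles it, and lists read in this way cannot also test the zones. Directions are therefore given as higher or lower in the experiment condition. No value per library was analysed here, so the depth of each library is unknown, and no SD or n stands beside a fold change.

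Among genes that passed the test, the largest finite rise in the authors' deposited table was that of AGP3, an arabinogalactan protein of the cell wall, with a log2 fold change of 10.14. LRX1, a leucine-rich repeat extensin of the root hair wall (8.54), RHS19, a root hair peroxidase (8.46), and RALF1, a secreted signalling peptide (7.84), were also among the largest rises of called genes with a symbol in the authors' deposited table. The lipid-transfer family genes AT1G48750 (9.01), AT5G05960 (8.93) and AT3G18280 (8.83), which have no symbol, lay between AGP3 and LRX1 in the authors' deposited table. The loci behind AT1G48750 and AT5G05960 reach beyond the annotated genes, so these values are uncertain. The largest finite fall among called genes with a symbol in the authors' deposited table was that of AN3, a transcriptional coactivator that promotes cell proliferation (-7.86). GRF4, a growth-regulating factor of the family that AN3 binds, stood at -6.52 in the authors' deposited table.

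The other genes among the 10 called genes with a symbol and the largest finite rises in the authors' deposited table were the hydroxyproline-rich glycoprotein HRGP1 (8.21), GH9C1, a glycosyl hydrolase (7.69), the root hair regulator LRL3 (7.68), GASA1 (7.65), DMP2 (7.51) and the phenylpropanoid enzyme PAL4 (7.40). HRGP1 lies beside a near-identical copy, and its value is uncertain because reads can be split between the copies. Among the 10 largest finite falls of called genes with a symbol, the authors' deposited table also had the thaumatin-like ATLP-1 (-7.39), the transcription factor GATA2 (-6.81), ENODL14 (-6.51), NPY4 (-6.26), XTH5 (-5.78), the histone HTA8 (-5.72), the mechanosensitive channel MSL9 (-5.60) and the microRNA gene MIR779 (-5.56). Without a symbol, the lectin family gene AT1G52070 (-9.15), AT2G28790 (-7.93) and AT5G10130 (-7.22) also fell in the authors' deposited table, and the value of AT1G52070 is uncertain because its locus reaches far beyond the annotated gene. The q-values of the 10 rises with a symbol ran from 0.000177 to 0.00793 in the authors' deposited table, and those of the 10 falls with a symbol from 0.000177 to 0.00306. On the TAIR10 build, the authors' deposited table places AGP3 on chromosome 4 from 18580838 to 18581585 and LRX1 on chromosome 1 from 4070124 to 4072567. AN3 lies on chromosome 5 from 10647570 to 10649892 and GRF4 on chromosome 3 from 19616021 to 19618449, also from the authors' deposited table. All 4 are protein-coding genes in the reference annotation, and each of these spans lies within the annotated gene. The locus given for MIR779, on chromosome 2 from 9560112 to 9562020, is longer than the annotated hairpin, from 9560761 to 9560923.

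When genes were ranked by the test statistic in place of the fold, water channels and a further arabinogalactan protein were among the leading rises. The authors' deposited table had GAMMA-TIP, the tonoplast water channel also called TIP1;1, at 5.86, the copper chaperone CCH at 5.59, the plasma membrane water channel PIP2A at 5.26 and AGP2 at 4.79. The leading falls in the authors' deposited table were the arabinogalactan protein AGP31 (-4.40), ENODL15 (-4.81), the cyclophilin ROC2 (-3.55), the histone HTB2 (-4.13) and NAP57, a nucleolar pseudouridine synthase (-3.37). FIB2, the nucleolar protein fibrillarin, was at -2.92, and the wall loosening expansin EXPA15 was at -4.40, both with q = 0.000177 in the authors' deposited table.

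In all, 7863 of 18050 tested gene loci (43.6%) had a Cuffdiff q under 0.01 in the authors' deposited table. Of these, 4032 were higher and 3831 were lower in the experiment condition. The median log2 fold change of finite calls was 1.93 for rises and -1.65 for falls. Large changes were more often rises, with 850 genes at a log2 of 3 or more and 321 at -3 or less. A further 466 of the risen genes were listed at 0 in the control condition and 157 of the fallen genes at 0 in the experiment condition, and they have no fold. The median over all tested finite loci was -0.075. The other 15183 of 33233 loci had no test in the authors' deposited table. Cuffdiff gave no p below 5e-05, which 5093 genes shared, so that genes with q = 0.000177 cannot be ranked by their p.

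**Figure D1:**
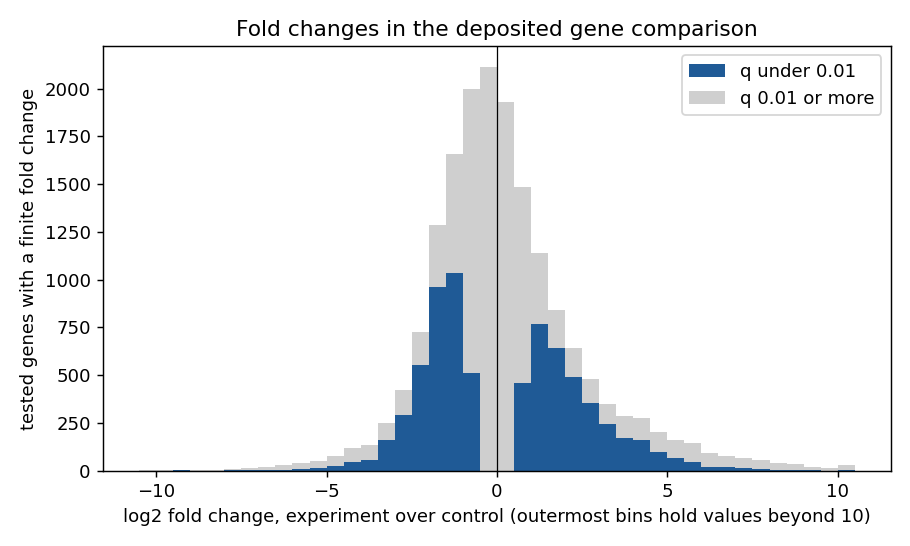
Histogram of the log2 fold change (experiment over control, horizontal axis) of tested genes with a finite value, with the number of genes on the vertical axis. Blue bars are genes with q under 0.01 and grey bars, stacked on them, are the other tested genes, and the called genes number 3566 above 0 and 3674 below.

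Genes of cell division were lower in the experiment condition. Of 25 tested genes of mitosis and the G2/M transition, 16 fell and none rose, and 16 fell when adjusted over the list alone. KNOLLE, a syntaxin of cell plate formation (-4.98), the anaphase activator CDC20.1 (-4.74), the mitotic cyclin CYCB1;1 (-3.95) and the spindle protein TPX2 (-3.87) were among the falls in the authors' deposited table. MAP65-3, a microtubule bundler of the phragmoplast, was listed at 0 in the experiment condition with q = 0.000177 in the authors' deposited table. The cyclins CYCB2;1 (-4.69, q = 0.0181) and CYCA1;1 (-4.18, q = 0.277) did not pass the test in the authors' deposited table. Of 17 tested DNA replication genes 9 fell, the same number as when adjusted over the list alone, and none rose. CYCA3;1 (-3.63), the origin licensing factor CDT1A (-3.31), the ribonucleotide reductase subunit TSO2 (-2.43) and the sliding clamp PCNA2 (-1.91) fell most in the authors' deposited table. CDC6 (-1.81, q = 0.0242) and MCM6 (-1.07, q = 0.0518) did not pass in the authors' deposited table. Core histones fell in 30 of 40 tested genes, also 30 when adjusted over the list alone, and the centromeric histone HTR12 was at -3.60 in the authors' deposited table. HTA12 was the 1 histone that rose, at 2.28 in the authors' deposited table.

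Ribosomal protein genes formed the largest group and moved the same way. Of 292 tested members, a list drawn by description that can include organellar proteins, 244 fell and 7 rose, against 245 and 7 when adjusted over the list alone. RPL16A was at -3.32 and the ubiquitin fusion gene AT1G23410 at -3.27 in the authors' deposited table, and AT5G63070 was listed at 0 in the experiment condition. The 7 that rose in the authors' deposited table were SSR16 (0.68), AT5G47190 (0.71), PSRP3/1 (1.05) and the L18ae family genes AT1G17080 (1.87), AT3G14595 (2.18), AT4G26060 (2.19) and AT1G53560 (3.49). Fisher's exact test (two-sided, Benjamini-Hochberg over 20 lists and both directions) gave an adjusted p for falls of 2.66e-115 for ribosomal proteins, 6.74e-12 for histones, 4.62e-05 for mitosis and 0.0144 for DNA replication. Here and for the other lists and gene families, this test treats genes as independent, although members of a list can move together. Its p-values therefore do not measure the spread between libraries. Rises were rarer than among other genes for ribosomal proteins, histones and mitosis, with adjusted p-values by Fisher's exact test of 1.06e-21, 0.00508 and 0.0116. The medians of these lists were -1.83, -1.94, -3.38 and -1.08, at percentiles 0, 0, 0 and 1.55 among 10000 random lists of the same sizes.

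Regulators of the stem cell niche and the root cap were lower where they passed. The meristem transcription factors PLT1, PLT2 and BBM and the peptides RGF2 and RGF3 were all listed at 0 in the experiment condition with q = 0.000177 in the authors' deposited table. With MGP (-1.30 in the authors' deposited table), 6 of 12 tested genes of this list fell and none rose, and 6 fell when adjusted over the list alone. PLT3 (-2.94, q = 0.193) and JKD (-0.63, q = 0.0149) did not pass in the authors' deposited table. Among 10 tested root cap genes 5 fell, and when adjusted over the list alone 5 fell and 1 rose. The cap transcription factors BRN1, BRN2 and FEZ were listed at 0 in the experiment condition, and the cellulase CEL5 (-5.45) and the auxin response factor ARF16 (-2.60) fell in the authors' deposited table. SMB, another cap regulator, was at -7.82 with q = 0.310, and the pectin lyase family gene AT1G65570 at -5.33 with q = 0.311 in the authors' deposited table. BFN1, a nuclease of dying cap cells, was at 4.09 with q = 0.0116 in the authors' deposited table. Fisher's exact test gave an adjusted p for falls of 0.0685 for the stem cell niche and 0.104 for the root cap. The list medians, with genes listed at 0 ranked last, were -2.12 and -5.39, at percentiles 0.01 and 0 among random lists. At a q under 0.05 the stem cell niche list passed, with an adjusted p of 0.0173.

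Root hair and elongation genes were higher in the experiment condition. Of 18 tested root hair genes 10 rose and 1 fell, the same as when adjusted over the list alone. Besides LRX1, RHS19 and LRL3, the root hair expansin EXPA7 (7.03) rose in the authors' deposited table, while RHD6, an early regulator of hair cell fate, fell (-1.23). AT4G26010, a peroxidase (11.00, q = 0.0337), and PRP1 (10.66, q = 0.304) did not pass in the authors' deposited table. Of 14 tested genes of elongation and the primary wall 11 rose and none fell, also when adjusted over the list alone. XTH18 (4.97) and XTH17 (3.95), which remodel xyloglucan, and the proton pump AHA2 (2.66) rose in the authors' deposited table. The water channel gene TIP2;3 (11.18, q = 0.310) and XTH20 (6.97, q = 0.306) did not pass in the authors' deposited table.

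Xylem genes rose in 7 of 13 tested members and fell in 1, and when adjusted over the list alone 8 rose and 1 fell. The laccase LAC4 (7.13), the secondary wall regulator MYB46 (5.59) and the protease XCP1 (5.05) rose, and VND6, a master regulator of vessel formation, was listed at 0 in the control condition in the authors' deposited table. ACL5, a spermine synthase family gene that delays vessel differentiation, fell (-1.16 in the authors' deposited table). LAC17 (8.35, q = 0.310) and IRX9 (7.76, q = 0.288) did not pass in the authors' deposited table. Of 6 tested phloem genes 4 rose, also when adjusted over the list alone, led by the sucrose transporter SUC2 (5.07) and the callose synthase CALS7 (3.33) in the authors' deposited table. SEOR1, a sieve element protein, was at 6.52 with q = 0.305 in the authors' deposited table.

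The endodermal barrier list rose in 3 of 10 tested genes, also when adjusted over the list alone. These were the dirigent-like ESB1 (6.69), the transcription factor MYB36 (5.27) and CASP2, a Casparian strip membrane protein listed at 0 in the control condition in the authors' deposited table. Its relative CASP1 (14.11, q = 0.273) did not pass in the authors' deposited table. Nutrient transporters rose in 7 of 8 tested genes, and in 8 when adjusted over the list alone. The phosphate transporter PHT1;1 (6.94), the sulfate transporter SULTR1;2 (3.91) and the nitrate transporter NRT1.1 (2.72) rose, and AMT1;2 was listed at 0 in the control condition in the authors' deposited table. The potassium channel AKT1 was at 3.79 with q = 0.0141 in the authors' deposited table.

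Fisher's exact test gave an adjusted p for rises of 0.000100 for elongation and the primary wall, 0.00119 for nutrient uptake, 0.00990 for root hairs, 0.0436 for xylem, 0.0685 for phloem and 0.611 for the endodermal barrier. The medians in this order were 1.86, 3.73, 6.51, 5.05, 2.71 and 10.49, at percentiles 99.36, 99.81, 100, 100, 98.27 and 100 among random lists. Photosynthesis genes, a list fixed as markers of shoot tissue, rose with these groups in 8 of 12 tested genes, also when adjusted over the list alone (Fisher's exact adjusted p = 0.00633). The antenna protein gene LHCB3 (3.95), the Rubisco subunit genes RBCS3B (3.83) and RBCS1A (3.44) and Rubisco activase RCA (2.84) rose most in the authors' deposited table. LHCB1.1 (4.74, q = 0.119) and LHCB2.1 (3.63, q = 0.134) did not pass in the authors' deposited table. The list median was 3.04, at percentile 99.91 among random lists.

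**Figure D2:**
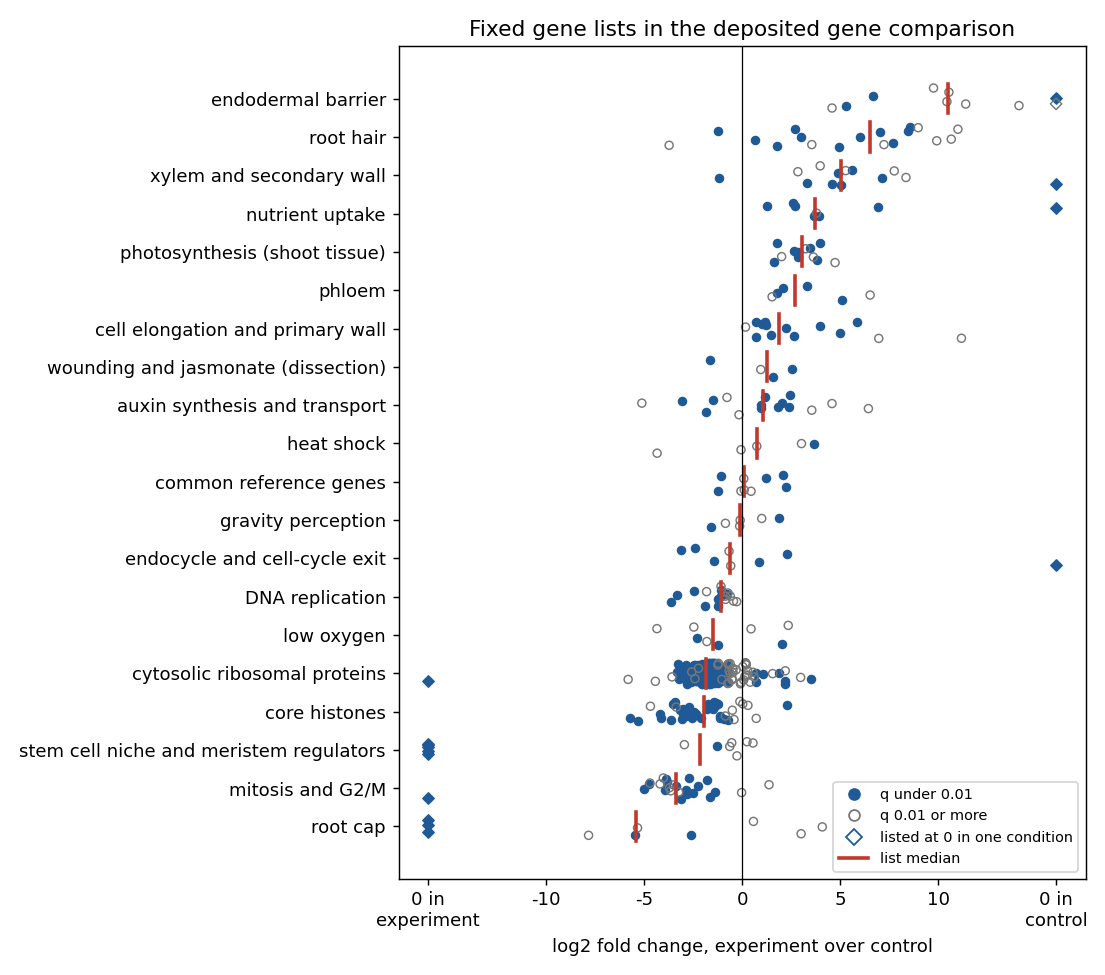
Log2 fold change (experiment over control, horizontal axis) of each tested member of the 20 gene lists, 1 line per list, ordered by the list median in red. Filled blue marks have q under 0.01, open grey marks do not, and diamonds at either edge are genes listed at 0 in one condition. The endodermal barrier median of 10.49 lies farthest to the right and the root cap median of -5.39 farthest to the left. Medians include genes that did not pass, which were 7 of 10 for the endodermal barrier and 5 of 10 for the root cap.

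Auxin genes moved both ways. Of 16 tested genes 7 rose and 3 fell, and when adjusted over the list alone 7 rose and 4 fell. The transporter ABCB4 (2.46), the biosynthetic enzyme YUC8 (2.38) and the influx carriers LAX3 (2.02) and AUX1 (1.82) rose in the authors' deposited table. The efflux carrier PIN2 (-3.04) and the biosynthetic enzyme TAA1 (-1.84) fell in the authors' deposited table, while PIN3 (0.97) and PIN7 (0.99) rose. YUC5 (6.44, q = 0.153) and LAX2 (-5.11, q = 0.0192) did not pass in the authors' deposited table. The list of cell-cycle exit and endocycle genes split as well, with 3 of 8 tested genes up and 3 down, also when adjusted over the list alone. Its members were not sorted by whether they promote or hold back the endocycle, so the split gives no direction for the process. The inhibitor KRP1 was listed at 0 in the control condition and KRP2 (2.31) and SIM (0.87) rose, whereas DEL1 (-3.14), WEE1 (-2.38) and SMR1 (-1.45) fell in the authors' deposited table. CCS52A1 (-0.66, q = 0.0208) and CCS52A2 (-0.58, q = 0.365) did not pass in the authors' deposited table. Of 6 tested gravity genes 1 rose and 1 fell, and when adjusted over the list alone 1 rose and none fell. SGR9 was at 1.89 and the starch enzyme PGM1 at -1.59, and SGR2 (1.00, q = 0.201) and SGR5 (-0.85, q = 0.0662) did not pass in the authors' deposited table.

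In the stress lists, called genes were 3 of 4 tested for wounding, 3 of 8 for low oxygen and 1 of 5 for heat shock. Among all tested genes the share was 43.6%. The jasmonate repressors JAZ1 (2.56) and JAZ2 (1.59) rose and OPR3 fell (-1.61) in the authors' deposited table, out of 4 tested genes of 12 in the wounding list, and 3 rose and 1 fell when adjusted over the list alone. AOS, an enzyme of jasmonate synthesis, was at 0.95 with q = 0.0106 in the authors' deposited table. In the low oxygen list 1 of 8 tested genes rose and 2 fell, also when adjusted over the list alone, with SUS1 at 2.04, LBD41 at -2.31 and PDC1 at -1.20 in the authors' deposited table. ADH1 (-4.34, q = 0.208) and AT3G10040 (-2.46, q = 0.0667) did not pass in the authors' deposited table. HSP70 (3.68 in the authors' deposited table) was the only riser among 5 tested heat shock genes, also when adjusted over the list alone. HSFA2 (-4.33, q = 0.297) and HSP18.2 (3.03, q = 0.0426) did not pass in the authors' deposited table.

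Of genes often used as constant references in plant work, 5 of 9 passed the test. Of these 9, 3 rose and 2 fell, also when adjusted over the list alone. UBQ10 (2.24), ACT8 (2.07) and ACT2 (1.23) rose, and the elongation factor gene AT5G60390 (-1.24) and the TIP41-like gene AT4G34270 (-1.09) fell in the authors' deposited table. UBC21 (0.46, q = 0.112), the SAND family gene AT2G28390 (0.11, q = 0.704), GAPC1 (0.09, q = 0.697) and PP2AA3 (-0.06, q = 0.838) did not pass in the authors' deposited table. Transcripts of the organelle genomes passed in 1 of 14 tested mitochondrial genes, a fall, and in 0 of 25 tested plastid genes by Cuffdiff (1 of them at an unadjusted p under 0.05), with medians of -0.47 and -0.44. For the auxin, endocycle, gravity, wounding, low oxygen, heat shock and reference lists, the lower of both adjusted p-values by Fisher's exact test was 0.142, 0.536, 1, 0.348, 0.816, 0.739 and 0.570. Their medians in this order were 1.08, -0.62, -0.11, 1.27, -1.50, 0.75 and 0.11, at percentiles 96.4, 19.41, 45.08, 84.37, 1.31, 77.8 and 57.5 among random lists.

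The share of tested genes that passed did not grow steadily with the fold. It was 74.6% of the 2266 genes with an absolute log2 of 2 to 3, but 7.38% of the 149 genes at 8 or more (11 genes, 95% Wilson interval 4.17% to 12.7%). Of the 727 tested genes listed at 0 in one condition, 85.7% passed (interval 83.0% to 88.1%). These intervals treat genes as independent. The labels do not say that the 3 libraries of a zone came from separate cultures, so the spread between them can be technical. How Cuffdiff used the libraries is not given in the sources used here, so what spread its p-values measure is unknown.

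**Figure D3:**
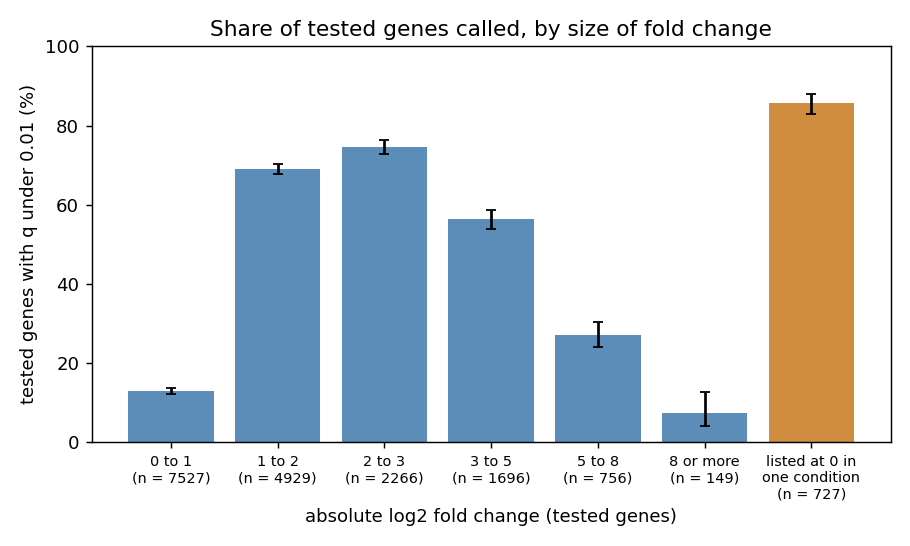
Percent of tested genes with q under 0.01 (vertical axis, from 0) by absolute log2 fold change (horizontal axis), with the number of tested genes under each bar and 95% Wilson intervals as error bars. The share is 74.6% at a log2 of 2 to 3 and 7.38% at 8 or more, and the orange bar, for genes listed at 0 in one condition, stands at 85.7%.

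At the level of isoforms, genes whose transcripts moved in opposite directions were rare. There were 2 among the 373 genes with at least 2 called isoforms (0.536%), out of 8779 genes with at least 2 tested isoforms. AT5G51880, an oxygenase family gene, had 1 isoform at 3.54 (q = 0.000428) and 1 at -2.12 (q = 0.00463) in the authors' deposited table. As a whole this gene was at -0.13 with q = 0.624 in the authors' deposited table of genes. AT1G30880, a gene of unknown function, had 1 isoform at 2.18 (q = 0.00186) and 1 at -2.93 (q = 0.000428), and the whole gene was at -2.08 (q = 0.000177), all from the authors' deposited tables. Both genes were named because of their isoforms, and no such gene was left at a q under 0.001, while 7 were found at a q under 0.05.

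Of 32807 tested isoforms, 5522 (16.8%) had a q under 0.01 in the authors' deposited table. Rises numbered 3257 and falls 2265, so that 59.0% of the called isoforms were higher in the experiment condition, against 51.3% of the called genes. The difference between these shares was not tested. Median log2 fold changes of finite calls were 2.07 and -1.62. Among the called isoforms, 428 were listed at 0 in the control condition and 140 in the experiment condition.

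Genes with a single isoform allow the gene and isoform comparisons to be set side by side, and 5530 such genes were tested in both. The comparisons cover different sets of loci and may rest on different assemblies. All 1852 of these genes that were called in both had the same direction, 742 were called as genes only and 130 as isoforms only. Calls were alike for 84.2% of these genes. Log2 values differed by less than 0.1 in 28.8% of the 5034 genes with finite values, and by less than 0.5 in 87.8%. The isoform value was the higher by a median of 0.12, and after each comparison was centred on its own median 38.5% differed by less than 0.1.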

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

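The counts of called genes and isoforms stayed within 1.5 times those reported under every alternative run. Protein-coding genes only, leaving out genes listed at 0, and both changes to the comparison of gene and isoform values were chosen after the data were seen. Called genes ranged from 5907 (q under 0.001) to 10072 (q under 0.05) and called isoforms from 4041 to 7581. The share of called genes that were higher in the experiment condition ranged from 49.3% to 53.7%, and that of isoforms from 57.1% to 60.4%. Genes with opposed isoforms numbered 7 at a q under 0.05 and 0 at a q under 0.001, and the alternative thresholds themselves set which isoforms count. Gene and isoform values lay within tolerance for 87.8% of genes at 0.5 and for 38.5% after centring. Of 20 lists, 9 were enriched among rises or falls as reported and 10 at a q under 0.05, when the stem cell niche was added (adjusted p 0.0173). Of 240 named genes and list members, 28 lost their call at a q under 0.001 and 23 gained one at 0.05. Centring shifts each fold change by the same small median and leaves q as it is, so it says little about stability. No paired analysis was possible because the tables hold 1 value per condition and none per library. For the same reason leaving out replicates, splits of the samples and camera were not run. Filters on expression, pseudocounts, rescaled values, q recomputed over expressed genes, expressed genes as list background, isoform sums against gene values and expression-matched random lists were not run either, because they need the condition values, which were not used here. Depth is unknown, so what it limits was not tested.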

Other observations

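The tests of gene families in this part were chosen after the data were seen, as was the test of a scaling error below. Several families of wall and surface proteins were higher in the experiment condition beyond the share of all genes with a description, 22.8%. Of 42 tested peroxidases, which cross-link wall polymers or make reactive oxygen, 28 rose and 2 fell (Fisher's exact adjusted p = 9.83e-08 for rises), with AT5G17820 at 5.71 and AT3G21770 at 3.83 in the authors' deposited table. Arabinogalactan proteins rose in 18 of 26 tested genes and fell in 2 (Fisher's exact adjusted p = 1.64e-05). AGP24 was at 4.52 in the authors' deposited table, while AGP31 (-4.40) and AGP30 (-5.15) were the members that fell. Xyloglucan-modifying enzymes rose in 13 of 20 tested genes and fell in 2 (Fisher's exact adjusted p = 0.000942), with XTH21 at 3.71 and XTH9 at -1.24 in the authors' deposited table. Lipid-transfer proteins rose in 24 of 42 tested genes and fell in 5 (Fisher's exact adjusted p = 3.21e-05), with AT3G22600 at 6.33 in the authors' deposited table.

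Some transcription factor and kinase families were enriched among rises and others were not. Of 63 tested MYB genes 33 rose and 3 fell (Fisher's exact adjusted p = 1.16e-05), and 2 of those that fell, MYB66 (-4.40) and MYB23 (-2.88 in the authors' deposited table), specify epidermal cells without hairs. MYB63, an activator of lignin genes, was at 4.40 in the authors' deposited table. Dof genes rose in 12 of 18, CBL-interacting kinases in 11 of 17 and WRKY genes in 15 of 34 tested members (Fisher's exact adjusted p = 0.00120, 0.00320 and 0.0372). NAC genes rose in 10 of 37 and Integrase-type factors in 11 of 43 tested members, and neither passed (Fisher's exact adjusted p = 0.739 and 0.876). CIPK15 was at 2.46 and WRKY69 at 3.44 in the authors' deposited table. Falls made up 21.4% of all genes with a description. Small nuclear ribonucleoproteins, parts of the splicing machinery, fell in 18 of 21 tested genes and DEAD-box helicases in 13 of 18, and none rose in either (Fisher's exact adjusted p = 4.84e-08 and 0.000106). Pseudouridine synthases fell in 9 of 17 (Fisher's exact adjusted p = 0.0288). Pentatricopeptide repeat proteins, which bind organelle RNA, fell in 35 of 119, which did not pass for falls (Fisher's exact adjusted p = 0.139), but rose in only 1, a share below that of all genes (Fisher's exact adjusted p = 5.29e-10). KH domain RNA-binding proteins fell in 4 of 16 and did not pass (Fisher's exact adjusted p = 0.882). LSM3A was at -2.05, the helicase STRS2 at -3.44 and the pseudouridine synthase AT1G76120 at -2.71 in the authors' deposited table. In all, 15 of 123 families were enriched among rises and 8 among falls.

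Large finite fold changes rarely passed the test: 689 tested genes with an absolute log2 of at least 5 did not pass and 216 did, and CASP1, CASP4 (10.54) and CASP5 (10.44 in the authors' deposited table) did not pass where CASP2 did. Loci shared by several genes held 0.581% of the genes that did not pass, and the median gene length of those that did not pass was 1.02 times that of those that did, which argues against shared loci and short genes. Estimates that scatter evenly in both directions would put about as many genes above 0 as below. Of those that did not pass, 80.1% were higher in the experiment condition (95% Wilson interval 77.0% to 82.9%), close to the 83.3% of those that passed. This share cannot exclude uneven scatter from values near 0 in one condition. Of tested genes, 535 were listed at 0 in the control condition and 192 in the experiment condition. Few reads in one condition, or a wide spread between its libraries, may keep genes with large folds from passing. Both stay open, as does a biological difference between the sections. None of these was tested, because the condition values were not used here and no value per library was analysed.

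Photosynthesis genes rose in the experiment condition, and pieces of shoot in a section are a candidate source. From a list of 12 other leaf and shoot genes fixed before its values were seen, 9 had no test and 3 did, of which 2 rose. Their median log2 of 1.71 is the value of CER1, the only tested member with a finite fold. Those without a test went no single way. FIL and CER6 were listed at 0 in the control condition and PDF1, ATML1 and STM at 0 in the experiment condition. YAB3, YAB5, KAT1 and FAMA had a log2 of 0. CER1, a wax gene, was at 1.71, and MYB60, a guard cell gene, was listed at 0 in the control condition, both called in the authors' deposited table, while AS2 was listed at 0 in the experiment condition with q = 0.0490. These values meet what had been written beforehand for pieces of shoot (at least 50% of the tested genes called higher and a median of at least 1.5), but a minimum of 5 tested genes was applied to it after they were seen, since 3 genes are too few to decide. Genes of the plastid genome did not rise with the photosynthesis list, with 0 of 25 tested genes called higher and a median log2 of -0.44. How pieces of shoot would change plastid transcripts in these libraries was not tested. Pieces of shoot therefore cannot be told apart from expression of photosynthesis genes in light-grown roots. A difference in tissue between the sections stays open and untested.

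Of the reference genes that passed, UBQ10, ACT8 and ACT2 rose while AT5G60390 and AT4G34270 fell. A scaling error between conditions would move all of them alike, but they spanned 3.48 on the log2 scale. A scaling error alone therefore cannot give these values. The same shift in every gene leaves the span as it is, so a scaling error on top of other differences is not excluded. Reads moved between near-identical copies would make a copy of each move the other way, but 0 of the 3 gene families examined had a copy that passed the test the other way. This does not exclude moved reads, since a copy that loses reads need not pass the test. UBQ3 could not be told from a neighbour or a duplicate and was left out, and ACT12 had no test. Whether the copies examined are the nearest ones was not checked. Of the tested copies, 1 of 4 actins (ACT11, 2.35) and 2 of 3 ubiquitins (UBQ11, 1.27, and UBQ14, 0.63) rose and 3 of 3 elongation factors fell in the authors' deposited table, while ACT7 (0.41), ACT1 (0.23), ACT3 (-0.07) and UBQ4 (0.42) did not pass. These genes may differ between the sections themselves, a hypothesis found and examined on the same data.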
